A study of Mus musculus with 6 samples.

How the data were processed

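RNA from CD4+ T cells of mouse spleen and lymph nodes, cultured in vitro, was hybridised to 6 oligonucleotide arrays, 2 in each of the groups Control, RA and Ro. Per the labels, 2 ug of total RNA was amplified in a single round and labelled with biotin for each array. The deposited values are probe set intensity values on a linear scale, made by the authors with MAS5, per the submitters' processing notes, which give no version. The scaling target and the array software settings are not given in the sources used here. The linear scale was read from the values, which are above 0 and have array medians from 16.3 to 23.8. Means trimmed by 2% at each end ran from 116 to 179, so no scaling to a common trimmed mean was visible in them. MAS5 values of dim probe sets are noisy, and detection calls were not used here.

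Samples were grouped by their titles, which also give the replicate numbers. One title writes the third group as RO and the other as Ro, and both were taken as 1 group. A culture protocol is given only for Control replicate 2, and whether the other 5 arrays share it is not given in the sources used here. The labels do not say that replicates come from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. No pair of arrays held identical data (at most 0.00443% of values agreed).

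Genes were named from GEO's platform annotation, in which 34958 probe sets have 1 gene symbol, 932 have several and 9211 have none. Symbols were checked through the Entrez ID, which changed 0 of them, and a probe set with several symbols was left unnamed. No genome build is named, so no coordinates are given. The 64 control probe sets were left out. A probe set was tested if it lay above the 40th percentile of its array on at least 2 of the 6 arrays, which left 29507 probe sets and 12986 genes. For a fit of 2 groups the same filter was applied to their 4 arrays, which left 27878 probe sets for RA and Ro.

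Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with an intensity trend) on log2(signal + 2.999), where the pseudocount is the 20th percentile of all deposited values and makes differences of dim genes look smaller. Each test allowed for both directions, and p-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, with a threshold of 0.05. All 6 arrays entered 1 fit with 3 residual degrees of freedom and no block. The values were used as deposited. Because the median log2 difference of all tested probe sets was 0.09 for RA minus Control, 0.29 for Ro minus Control and -0.21 for RA minus Ro, against 0.02, 0.02 and -0.00076 after quantile normalization, log2 differences of genes are given relative to that median and those of lists relative to the median gene. Signals, their SDs and folds of mean signals are given without that correction.

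Each gene was represented by its tested probe set with the highest mean log2 value, leaving out probe sets marked as cross-hybridising where the gene had another. The genes named were fixed by a rule. In each comparison up to 8 genes with the largest increase and 8 with the largest decrease were to be named among those past the threshold without overlap of the groups. Where fewer passed, the list was filled up to 5 by the smallest unadjusted p, given as values only. In each gene list described, up to 4 members past the threshold were named, or otherwise up to 2 with the largest difference, and 32 T cell genes were to be named whatever their values where analysed. Fam102b, Nacc2, Fcer1a, Mki67, Eif2s3y and the further genes of the closing section were named after their values were seen.

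The 26 gene lists, with 530 members of which 416 were measured, covered retinoid response, gut homing, T helper states, signalling, metabolism and markers of other cell types. They were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over 78 tests, and 29 were called. With an estimated correlation 0 were called and 5 had an unadjusted p under 0.05, and with fry 0 were called and 5 had an unadjusted p under 0.05. For some of the 29 lists the estimate lay below the preset 0.01. A call lost with an estimated correlation thus does not by itself show that the members of a list were correlated. The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were a pseudocount of 1 or at the median of all values, quantile normalization, no filter or a filter at the 60th percentile, no intensity trend, the replicate number as a block, gene means, a fit of only the groups compared, a 2-fold criterion without overlap, and leaving out each array. Further settings of the 4-array fit, leaving out its arrays in turn included, camera on those arrays, and the directions without 1 array of named genes given as signals were added after seeing the data. So was a simulation with a spread for the Control arrays and another, pooled, for the RA and Ro arrays. The relation of the effects was compared with 100 simulations of unchanged groups.

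The tests were tried on simulated data for RA versus Ro with 50 probe sets changed at each of 4 sizes. Each simulated probe set had 1 spread for all its arrays, and the changed ones were drawn from those with a mean above the median. The fit of all 6 arrays, over 29507 probe sets, recovered 0, 0, 22 and 72% of log2 changes of 1, 2, 3 and 4, and the fit of the 4 arrays, over 27878 probe sets, recovered 10, 62, 96 and 100%. Unchanged probe sets called numbered 4 and 5. In the simulated fit of all 6 arrays 4.97% of unchanged probe sets had an unadjusted limma p under 0.05, whereas in the data 496 of 29507 did. The data thus lack the common spread of the simulation, so its recovery does not describe that fit, nor dim probe sets in either fit.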

Results

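Transcript levels were measured in cultured mouse CD4+ T cells, the helper class of T lymphocytes, taken from spleen and lymph nodes. The 6 oligonucleotide arrays, each with 45101 probe sets, fell into 3 groups of 2 arrays, labelled Control, RA and Ro. RA is retinoic acid, the vitamin A metabolite named in the title of the series, and the labels do not expand Ro. The median signal of an array lay between 16.3 and 23.8 arbitrary units. Among the 5 arrays other than Control replicate 2, the correlation of log2 values across probe sets was 0.947 to 0.970, whereas Control replicate 2 correlated with them at only 0.869 to 0.880. That array was also the only one whose label gives a culture protocol, a mixture of cytokines and blocking antibodies for 5 days. The label lists IL2, TGFb1, IL6, IL1b, IL23, IL21 and TNFa, with antibodies against IL4 and IFNg. The number of arrays limits the precision of every value that follows.

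The comparison of RA with Ro asks which T cell genes differ between the cultures with these labels. The Control arrays enter it through the filter and the spread in the fit of all 6 arrays, and not at all in the fit of the 4 RA and Ro arrays. Ccr9, the chemokine receptor that directs T cells to the small intestine, had a mean signal of 453 ± 78.7 (SD, n = 2) in RA and 7.34 ± 2.24 (SD, n = 2) in Ro, and its 5 probe sets gave log2 differences from 1.77 to 6.26 in the fit of all arrays. Cyp26b1, a cytochrome that degrades retinoic acid, stood at 101 ± 20.1 in RA and 2.74 ± 1.37 in Ro. Both genes were so dim in Ro that the size of these differences is uncertain. P2rx7, an ATP-gated ion channel, was 10.5-fold higher in RA (760 ± 64.7 against 72.6 ± 8.01), and Fam102b was 5.17-fold higher (2292 ± 189 against 443 ± 115). In the other direction, Cma1 and Tph1, the mast cell chymase and the enzyme that starts serotonin synthesis outside the brain, stood at 505 ± 18.7 and 218 ± 23.9 in Ro and 38.9 ± 7.05 and 12.4 ± 4.58 in RA. Nacc2, a transcriptional repressor, was 8.92-fold higher in Ro (559 ± 9.68 against 62.6 ± 21.7).

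These 7 genes, with 12 probe sets, were the ones that passed an adjusted p of 0.05 when limma was fitted to the 4 RA and Ro arrays alone. The log2 differences of RA minus Ro in that fit were 5.69 (SE 0.32) for Ccr9, 4.41 (SE 0.41) for Cyp26b1, 3.55 (SE 0.27) for P2rx7 and 2.60 (SE 0.25) for Fam102b, and -3.39 (SE 0.29) for Cma1, -3.65 (SE 0.34) for Tph1 and -2.92 (SE 0.32) for Nacc2. Tph1 was dim in RA, at 9.17 and 15.6, so the size of its difference is uncertain too. Adjusted p values ran from 0.00474 to 0.0445. Of the tested probe sets, 3 of 5 for Ccr9, 2 of 3 for P2rx7 and 2 of 4 for Nacc2 passed, and the rest had the same direction. The limma fit of all 6 arrays, which was the test chosen beforehand, called 0 of 29507 probe sets, with 496 at an unadjusted p under 0.05 where 1475 would be expected by chance. The unlike Control arrays widened the spread in that fit: the SE of Cma1 was 1.03 there and 0.29 in the 4-array fit, and that of Cpa3 1.52 and 0.23. Its 0 calls are therefore weak evidence against differences between RA and Ro. The 12 calls of the 4-array fit fell to 0 without an intensity trend in the variance, to 4 with a stricter filter on dim probe sets, and to 0 without RA replicate 1 or RA replicate 2. Without Ro replicate 1 there were 551 and without Ro replicate 2 there were 425, in fits that were added after seeing the data and assume that the lone array varies like the other group. With the replicate number as a block, also added after seeing the data, there were 106. Among them were probe sets of Dhrs3, Itga4, Nrp1, Nt5e, Il12rb2 and Cpa3, a result that holds only if the replicate numbers pair the RA and Ro arrays. Over all settings tried, the limma adjusted p of Ccr9 ran from 4.46e-22 to 1.00, and that of Cyp26b1 from 6.39e-12 to 1.00. A criterion without a test, a 2-fold difference with no overlap between the arrays of the groups, was met by 1383 probe sets, 417 higher and 966 lower in RA. With each array centred on its median it was met by 1256, 753 higher and 503 lower, but a split of the same 4 arrays by replicate number met it for 1717. No overlap alone, without the 2-fold difference, was found for 40.7% of tested probe sets before centring, with the general shift between the groups left in. Chance alone separates 2 arrays from 2 in that sense for 33.3% of probe sets, so this share is not to be set against the counts of the 2-fold criterion.

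**Figure D1:**
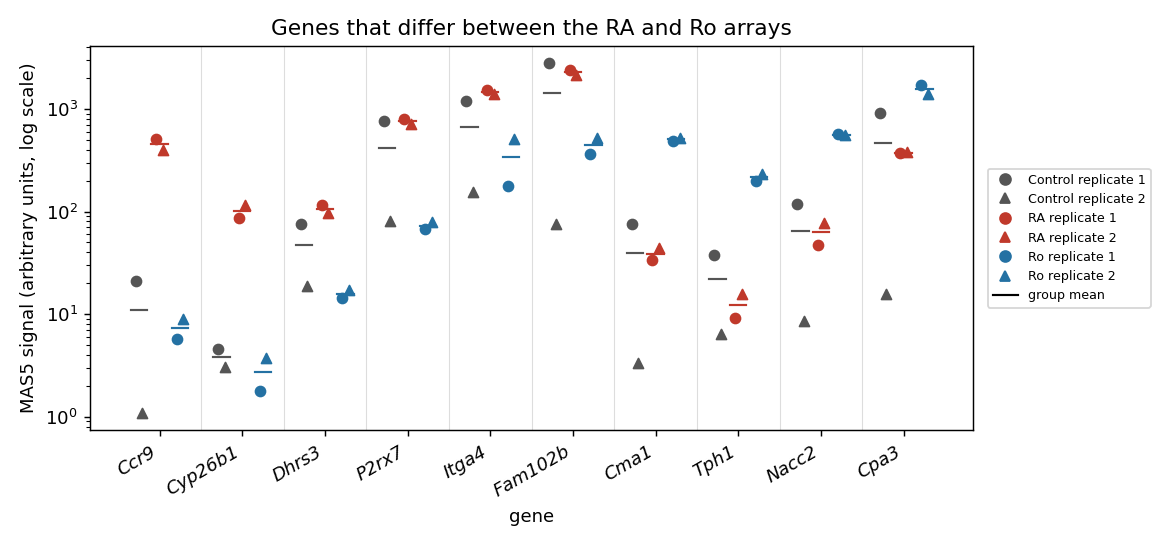
Signal of 10 genes on each array, on a log axis in arbitrary MAS5 units, with circles for replicate 1, triangles for replicate 2 and short lines for the mean of each group. The RA arrays lie above the Ro arrays for Ccr9, Cyp26b1, Dhrs3, P2rx7, Itga4 and Fam102b and below them for Cma1, Tph1, Nacc2 and Cpa3, and Control replicate 2 lies far from Control replicate 1 for most of these genes.

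Genes of retinoid response and metabolism were higher in RA than in Ro as a list. Of 15 measured members, 10 lay above the median gene, with a list median of 0.64 on the log2 scale (camera adjusted p = 2.02e-05). With an estimated correlation the call was lost (camera unadjusted p = 0.0152 and adjusted p = 0.583 with an estimated correlation). The estimate for this list was -0.0045, below the preset 0.01, so a higher correlation among its members did not remove the call. Its larger p came with the 3 residual degrees of freedom that camera uses with an estimate. The list median was only 0.09 without Ro replicate 2 and 0.34 without RA replicate 1. None passed over all genes tested, and 2 passed adjusted over the list alone, or 5 in the fit of the 4 arrays. Besides Cyp26b1, Dhrs3, a reductase that returns retinaldehyde to retinol, had a signal of 106 ± 13.8 in RA and 15.7 ± 1.82 in Ro, a log2 difference of 2.75 (SE 0.62) in the fit of all arrays. The corepressor gene Hic1 stood at 195 ± 23.3 in RA and 55.8 ± 11.1 in Ro. The receptor genes went the other way in value: Rarg had a signal of 106 ± 1.41 in RA and 217 ± 27.5 in Ro, and Rara 51.1 ± 25.1 and 78.9 ± 10.7. Rarb was below the filter on dim probe sets, with signals from 0.308 to 4.71 over the 6 arrays.

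The gut homing list, which holds Ccr9 and P2rx7, was also higher in RA, with 5 of 8 members above the median gene and a list median of 0.48 (camera adjusted p = 8.09e-05, and adjusted p = 0.583 with an estimated correlation). Its estimated correlation of -0.055 was also below the preset one, so a higher correlation among its members did not remove this call either. The camera unadjusted p of the list with that estimate was 0.0204. Its median was 0.29 without Ro replicate 2 and 0.31 without RA replicate 1. The count was 0 over all genes tested and 2 adjusted over the list alone, or 3 in the fit of the 4 arrays. Itga4, the integrin alpha chain that pairs with the Itgb7 product for adhesion in the gut wall, had a signal of 1474 ± 89.6 in RA and 341 ± 231 in Ro, a log2 difference of 2.50 (SE 0.92). Its partner Itgb7 stood at 2591 ± 471 in RA and 3394 ± 447 in Ro. Itgae and Gpr15, which also serve mucosal homing, had mean signals of 25.8 and 3.29 in RA and 24.7 and 13.7 in Ro.

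The interferon response list lay lower in RA than in Ro: 31 of 32 measured members were below the median gene, and for 28 of 32 both RA arrays were below both Ro arrays. The list median was -1.13 on the log2 scale (camera adjusted p = 5.41e-10, and adjusted p = 0.618 with an estimated correlation). None passed over all genes tested and 0 passed adjusted over the list alone with all 6 arrays in limma, where 7 had an unadjusted p under 0.05. In the fit of the 4 arrays 28 passed adjusted over the list alone. Ifit3, an antiviral effector, had signals of 126 and 515 on the RA arrays and 2799 and 1538 on the Ro arrays, and Oasl2 had 74.6 and 142 against 1074 and 243. The Th1 list, genes of the interferon gamma-producing helper state, was lower in RA as well (17 of 20 below the median gene, list median -0.83, camera adjusted p = 0.00196, and adjusted p = 0.583 with an estimated correlation). Its call was lost without Ro replicate 1, at a list median of -0.44, and the median was -0.42 without RA replicate 1. The count for Th1 was 0 over all genes and 7 adjusted over the list alone in the fit of the 4 arrays. Il12rb2, a chain of the interleukin 12 receptor, had a signal of 32.3 ± 18.7 in RA and 127 ± 14.0 in Ro, and Havcr2 4.99 ± 5.49 and 34.1 ± 20.3.

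Of the other lists called between RA and Ro, glycolysis and hypoxia genes were higher in RA, with 20 of 25 above the median gene and a list median of 0.32 (camera adjusted p = 0.00206, and adjusted p = 0.786 with an estimated correlation). Bnip3, a hypoxia-induced mitochondrial gene, had signals of 647 ± 38.5 in RA and 295 ± 17.0 in Ro, and the glycolytic enzyme gene Tpi1 2563 ± 155 and 1478 ± 24.5. Without Ro replicate 1 that call was lost, at 0.26. The estimated correlation was 0.69 for the glycolysis list and 0.79 for the cell cycle list, far above the preset 0.01. The list of other trafficking receptors and selectin ligands was lower in RA (23 of 29 below the median gene, list median -0.26, camera adjusted p = 0.00910, and adjusted p = 0.583 with an estimated correlation), and its call was lost without Ro replicate 1 (-0.12) and without RA replicate 2 (-0.25), with medians of -0.13 without RA replicate 1 and -0.51 without Ro replicate 2. Ccr8 had mean signals of 24.1 in RA and 101 in Ro. Cell cycle genes were higher in RA over the 41 members measured (list median 0.42, camera adjusted p = 0.00124, and adjusted p = 0.820 with an estimated correlation), with Plk1 at 1088 ± 304 in RA and 793 ± 653 in Ro and Tk1 at 781 ± 191 and 822 ± 953. Without Ro replicate 2 the direction turned, to -0.37 with a camera adjusted p of 1.37e-04, and without RA replicate 1 the call was lost (0.21). The median was 1.40 without Ro replicate 1 and 0.72 without RA replicate 2. For Plk1 and Tk1 the log2 differences of 0.94 and 0.91 turned to -0.07 and -0.79 without Ro replicate 2. The mean signal of Tk1 was itself lower in RA than in Ro. The Treg list, genes of regulatory T cells, had a median of only 0.06 and a mean of 0.31 (camera adjusted p = 0.0309, and adjusted p = 0.786 with an estimated correlation), and its call was lost without RA replicate 1 (0.01) and without Ro replicate 2, where the median turned to -0.15. Without Ro replicate 1 it was 0.53 and without RA replicate 2 it was 0.17. Nrp1 and Nt5e, a neuropilin and an ectonucleotidase that makes adenosine, had signals of 133 ± 37.7 and 369 ± 24.0 in RA and 28.1 ± 16.2 and 84.3 ± 21.4 in Ro. The remaining 18 lists had camera adjusted p values from 0.109 to 0.933. With camera on the 4 RA and Ro arrays alone, added after seeing the data, 12 lists were called at the preset correlation and 0 with an estimated one. The 12 included 4 of the 18, all lower in RA: cytotoxic granule (-0.76, adjusted p = 0.0289), naive and quiescence (-0.09, adjusted p = 0.0317), NK cell markers (-0.71, adjusted p = 0.0467) and CD8 T cell markers (-0.97, adjusted p = 0.0476). None of these 4 kept its call without each array in turn: cytotoxic granule lost it without RA replicate 2 (-0.66) and turned without Ro replicate 1 (0.14), naive and quiescence lost it without RA replicate 1 (-0.07) and turned without Ro replicate 2 (0.15), but stood at -0.30 without Ro replicate 1, NK cell markers lost it without RA replicate 1 (-0.56) or Ro replicate 1 (-0.14) and stood at -1.10 without RA replicate 2, and CD8 T cell markers without any 1 of RA replicate 1, RA replicate 2, Ro replicate 1 and Ro replicate 2 (-0.80, -1.15, -1.15 and -0.78).

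Single genes outside these lists also separated the RA and Ro arrays, without passing the test on all 6 arrays. Fcrl1, Morc1 and Osgin1 were higher in RA by value, with mean signals of 77.1, 22.1 and 70.5 in RA and 8.09, 0.499 and 11.0 in Ro. Rgmb, a coreceptor for bone morphogenetic proteins, Rab38 and the mast cell protease gene Tpsg1 were lower in RA by value, with 9.36, 12.2 and 3.61 in RA and 85.1, 84.0 and 30.8 in Ro. The lower of these signals are too dim for the size of the differences to be given. Mxd1, an antagonist of Myc, was lower by value at -1.58 (SE 0.35). Other markers of mast cells and basophils had lower values in RA, without passing in the limma fit of all 6 arrays or, without a block, of the 4 arrays. Cpa3 had a signal of 376 ± 8.72 in RA and 1561 ± 213 in Ro, Fcer1a 170 ± 33.8 and 403 ± 9.18, and Mcpt8 680 ± 121 and 1834 ± 1081. The granulocyte and mast cell list as a whole was not called (11 measured, list median -0.01, camera adjusted p = 0.634). The T cell identity list was not called either (12 measured, list median 0.08, camera adjusted p = 0.858).

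**Figure D2:**
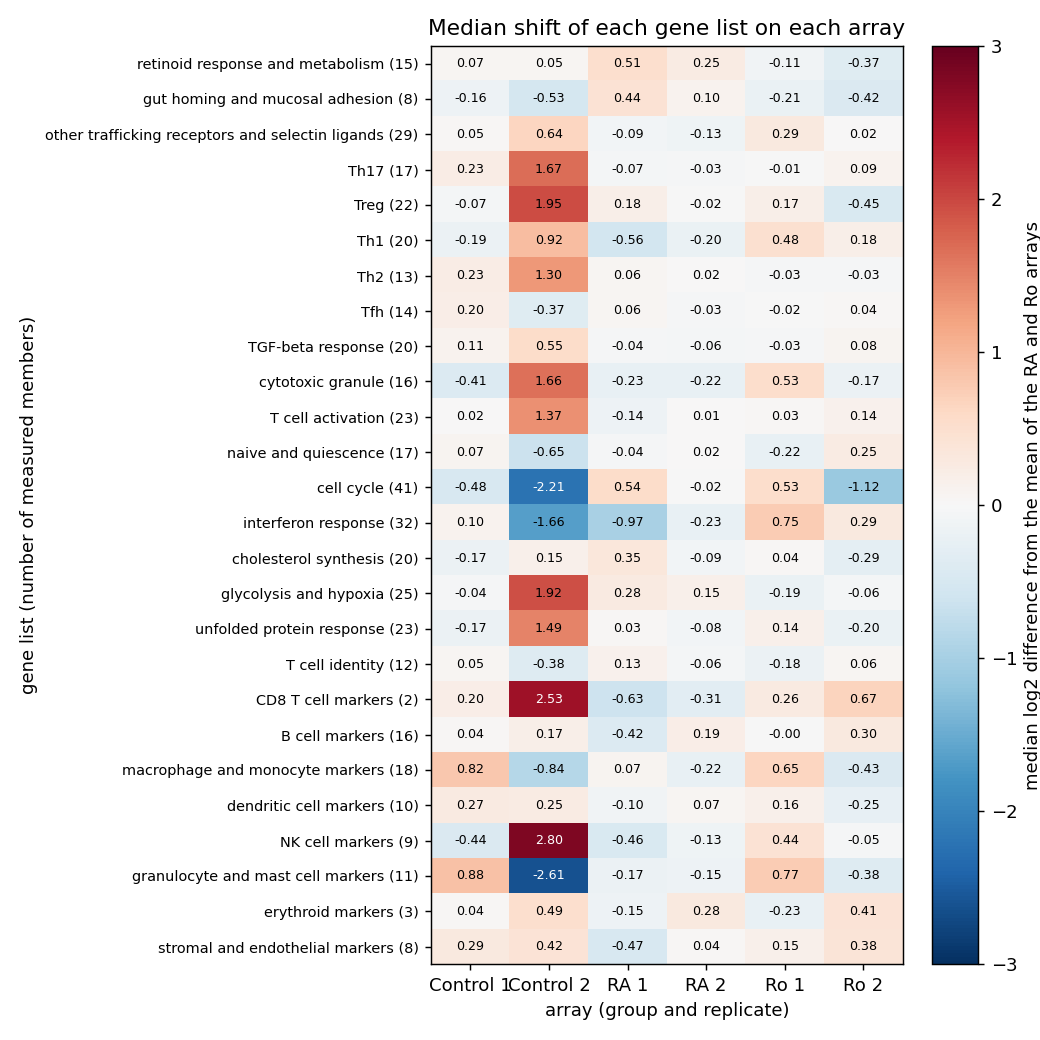
Median log2 difference of each gene list on each array from the mean of the RA and Ro arrays, with the number of measured members in parentheses, red for higher and blue for lower. Control replicate 2 carries the strongest shifts, among them 1.67 for Th17 and -2.21 for the cell cycle, whereas the retinoid list is positive on both RA arrays (0.51 and 0.25) and negative on both Ro arrays (-0.11 and -0.37).

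The comparison of RA with Control asks which genes differ between the cultures with these labels. It cannot tell an effect of retinoic acid from other differences of the Control arrays. Control replicate 2 had the Y-linked gene Eif2s3y at 0.972, against 747 to 967 on the RA and Ro arrays, and only its label gives a culture protocol. Cyp26b1 had a mean signal of 101 ± 20.1 (SD, n = 2) in RA and 3.78 ± 1.04 (SD, n = 2) in Control, and Ccr9 453 ± 78.7 and 11.0 ± 14.0, so that both RA arrays lay above both Control arrays. Their log2 differences were 3.85 (SE 0.49) and 5.43 (SE 0.79), but both genes were so dim in Control that these sizes are uncertain. The next 3 genes by unadjusted p were S100a5, Bard1 and Sult1a1, with dim mean signals of 20.2, 23.7 and 13.8 in RA and 1.22, 1.92 and 1.34 in Control. Lower in RA by value were Xist, the noncoding RNA of the inactive X chromosome, at -6.58 (SE 0.82), and Tmprss6, H2-T18, Syt5 and Wfdc2, with dim mean signals of 4.52, 1.70, 5.07 and 2.61 in RA and 25.6, 18.3, 28.5 and 29.8 in Control. Xist had signals of 680 and 4326 on the Control arrays and from 13.1 to 22.7 on the others.

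No probe set passed in the limma fit of all 6 arrays, where 0 were called and 535 had an unadjusted p under 0.05, against 1475 expected by chance, with a lowest adjusted p of 0.113. The limma fit of the RA and Control arrays alone also called 0. The criterion of a 2-fold difference without overlap was met by 1852 probe sets, 903 higher and 949 lower. With Control replicate 1 left out 4372 probe sets were called, and without Control replicate 2 the count was 0. In such fits the lone Control array is assumed to vary like the RA and Ro groups, which supply all of the spread.

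Between RA and Control 11 lists were called by camera, and none with an estimated correlation, where the adjusted p of these lists ran from 0.583 to 0.649 with an estimated correlation. Cell cycle genes were higher in RA (40 of 41 above the median gene, list median 1.72). Without Control replicate 2 the list median was 0.70, and without Control replicate 1 it was 2.74. The mitotic genes Cenpf and Kif11 had signals of 860 and 415 on Control replicate 1, 33.2 and 30.9 on Control replicate 2, and means of 1305 and 833 in RA. Lower in RA were Th17 (16 of 17 below the median gene, list median -1.04), T cell activation (-0.69), Th1 (-0.89), Th2 (-0.66), CD8 T cell markers (-1.79, only 2 members), TGF-beta response (-0.38) and the other trafficking receptors (-0.44). Without Control replicate 2 the medians of Th17, TGF-beta response and the other trafficking receptors were smaller (-0.34, -0.17 and -0.26), with the call kept. Without Control replicate 1 the medians of Th17, T cell activation, Th1 and CD8 T cell markers were -1.67, -1.19, -1.50 and -2.90. The cytokine genes Il2, Il24 and Il9 had 2288, 1068 and 252 on Control replicate 2, 56.9, 13.0 and 13.1 on Control replicate 1, and means of 38.4, 11.2 and 7.46 in RA. The chemokine genes Xcl1 and Ccl4 had 1802 and 4126 on Control replicate 2, 26.6 and 124 on Control replicate 1 and means of 17.4 and 63.2 in RA. Nr4a2, Cd8a, Cd8b1 and Tgfbi, a matrix protein induced by TGF-beta, had 342, 236, 85.0 and 36.0 on Control replicate 2, 27.9, 11.4, 124 and 14.8 on Control replicate 1, and means of 18.1, 5.38, 70.6 and 1.48 in RA. The calls of T cell activation, Th1, Th2 and CD8 T cell markers were lost without Control replicate 2, at -0.08, 0.01, -0.12 and -0.67. Glycolysis and hypoxia, the unfolded protein response and Treg were lower as well (-0.67, -0.80 and -0.75), but turned direction without Control replicate 2, to 0.27 (camera adjusted p = 0.00193), 0.09 and 0.17, and were -1.50, -1.68 and -1.62 without Control replicate 1. For Egln3 and Hk2, Atf3 and Chac1, and Itgae and Tnfrsf9, the members of these lists with the largest log2 differences, Control replicate 2 had 3163, 1176, 202, 406, 678 and 3173, Control replicate 1 had 72.4, 126, 28.3, 39.9, 15.7 and 433, and the RA means were 102, 120, 24.8, 45.1, 25.8 and 391. The calls of Th1 and CD8 T cell markers were also lost without RA replicate 1 (-0.86 and -1.63), and that of Th2 without RA replicate 2 (-0.53) or Control replicate 1 (-0.90). Without RA replicate 1 the Th2 median was -1.07. The retinoid and gut homing lists were not called against Control (list medians 0.01 and 0.43, camera adjusted p = 0.266 and 0.235). Of their other members, the transglutaminase gene Tgm2 and Gpr15 had 1857 and 1040 on Control replicate 2, 47.4 and 3.55 on Control replicate 1, and means of 66.0 and 3.29 in RA. In each of those lists 1 gene passed adjusted over the list alone and 0 over all genes.

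The comparison of Ro with Control asks the same for the cultures labelled Ro, and the Control arrays limit it in the same way. Tph1 had a signal of 218 ± 23.9 (SD, n = 2) in Ro and 22.0 ± 22.0 (SD, n = 2) in Control, and Cma1 505 ± 18.7 and 39.6 ± 51.3, with log2 differences of 3.20 (SE 0.69) and 4.22 (SE 1.03). That of Cma1 was 2.64 without Control replicate 2. Col27a1, Rgmb and Slc45a3 were also higher by value, with mean signals of 41.0, 85.1 and 21.5 in Ro and dim ones of 6.35, 15.9 and 1.18 in Control, although a second probe set of Col27a1 stood at -0.60. Lower in Ro by value were Xist, at -6.67 (SE 0.82), the ectonucleotidase gene Nt5e at -3.07 (SE 0.54), Osgin1 at -2.77 (SE 0.50), Evi5 at -2.40 (SE 0.42) and Tnfsf11, the RANK ligand, at -2.16 (SE 0.40). Osgin1 was so dim in Ro that the size of its difference is uncertain. A dim probe set of Nt5e stood at 0.66, and another of Evi5 at -0.21.

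In the limma fit of all 6 arrays 0 probe sets were called, 1201 had an unadjusted p under 0.05 against 1475 expected by chance, and the lowest adjusted p was 0.661. The fit of the Ro and Control arrays alone called 0 too, and the 2-fold criterion without overlap was met by 3013 probe sets, 2157 higher and 856 lower. With each array centred on its median that split turned to 999 higher and 1618 lower, since the median log2 difference of all tested probe sets was 0.29. Without Control replicate 1 there were 7211 calls, under the same assumption about the lone array, and without Control replicate 2 there were 0.

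Between Ro and Control 10 lists were called by camera and 0 with an estimated correlation (adjusted p from 0.583 to 0.792 with an estimated correlation). The interferon response list was higher in Ro, with 30 of 32 members above the median gene and a list median of 1.38, or 0.40 without Control replicate 2 and 2.26 without Control replicate 1. Ifit3 and Oasl2 had mean signals of 2168 and 659 in Ro, and on the Control arrays 811 and 256 for replicate 1 and 18.4 and 1.36 for replicate 2. The retinoid list was lower (9 of 15 below the median gene, list median -0.57, camera adjusted p = 0.0372), with Tgm2 and Hic1 at means of 33.7 and 55.8 in Ro, 47.4 and 217 on Control replicate 1 and 1857 and 79.0 on Control replicate 2. That call was lost without Control replicate 1 (-0.60), without RA replicate 1 (-0.47) or RA replicate 2 (-0.48), and without Ro replicate 2 (-0.31), and the median was -0.16 without Control replicate 2 and -0.36 without Ro replicate 1. Cell cycle and naive and quiescence genes were higher (1.05 and 0.38) and glycolysis and hypoxia, Treg, Th17, unfolded protein response, T cell activation and Th2 genes lower (-1.09, -0.96, -0.81, -0.72, -0.58 and -0.60). Dapl1 and Cnr2 of the naive list had means of 2740 and 172 in Ro, 2565 and 119 on Control replicate 1 and 24.5 and 10.1 on Control replicate 2. Nrp1 and Nt5e of the Treg list had means of 28.1 and 84.3 in Ro, 107 and 349 on Control replicate 1 and 374 and 999 on Control replicate 2. Bnip3 of the glycolysis list and Asns of the unfolded protein list had means of 295 and 361 in Ro, 407 and 211 on Control replicate 1 and 3258 and 1956 on Control replicate 2. Without Control replicate 2 the unfolded protein response turned to 0.25, and the calls of the other 7 of these lists were lost, at 0.25, -0.03, -0.17, 0.00087, -0.16, 0.02 and -0.31 in the same order. Without Control replicate 1 the medians of these 8 lists except Th2 were further from 0, at 2.00, 0.80, -2.02, -1.81, -1.38, -1.21 and -1.07. The cell cycle call was also lost without Ro replicate 1 (0.25), the naive call without Ro replicate 2 (0.10) and the unfolded protein call without Ro replicate 2 (-0.51). The cell cycle median was 2.01 without Ro replicate 2, and those of the naive and Treg lists were 0.64 and -1.58 without Ro replicate 1. In the Treg list 2 genes passed adjusted over the list alone, and in the T cell activation list 1 did, with 0 over all genes.

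The limma F-test for any difference among the 3 groups called 0 probe sets, with 499 at an unadjusted p under 0.05. Leaving out Control replicate 2 gave 7 calls and leaving out Control replicate 1 gave 4642, again with the lone Control array assumed to vary like the other groups.

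Other T helper genes chosen before the data were examined had the following mean signals. Foxp3, the regulatory T cell factor, stood at 97.3 in Control, 42.2 in RA and 29.0 in Ro. Ctla4 stood at 3508, 2050 and 2603, and Il2ra at 1831, 587 and 669. These Control means rest largely on Control replicate 2, where Foxp3, Ctla4 and Il2ra had 154, 4554 and 3062 against 40.3, 2462 and 601 on Control replicate 1. Without it the log2 difference of RA minus Control turned to 0.26 for Foxp3 and 0.16 for Il2ra and was -0.07 for Ctla4, and that of Ro minus Control turned to 0.06 for Il2ra and 0.03 for Ctla4 and was -0.52 for Foxp3. The Control means of Il17a, Il21, Ifng and Ccr6 were 620, 785, 1029 and 283, set by Control replicate 2 alone, since Control replicate 1 had 10.9, 2.97, 3.86 and 33.0. The RA and Ro means were 13.5 and 14.3 for Il17a, 3.48 and 6.46 for Il21, 14.3 and 51.6 for Ifng, and 18.6 and 30.2 for Ccr6. Gata3, the Th2 factor, stood at 519 in Control, 785 in RA and 991 in Ro, and Il4 at 45.1, 30.2 and 27.8. Tbx21, the Th1 factor, stood at 126, 111 and 261, Rora at 362, 117 and 176, and Cxcr3 at 153, 255 and 446. Control replicate 2 had 84.4 for Gata3 and 596 for Rora, and Control replicate 1 had 953 and 128, so that without Control replicate 2 the differences from Control were -0.08 and 0.02 in RA and 0.01 and 0.39 in Ro. The RA minus Control difference of Tbx21 turned to 0.38 without RA replicate 1. The trafficking genes Selplg, Ccr7, Fut7 and Ccr4 stood at 4607, 3301, 133 and 133 in Control, 3997, 2623, 37.5 and 37.7 in RA, and 4671, 4451, 115 and 22.3 in Ro. Il17f, Il22 and Il23r were not analysed here, and Il10, with a signal of 612 on Control replicate 2 and at most 11.3 elsewhere, did not pass the filter on dim probe sets.

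The RA and Ro effects were related through their shared Control arrays. Across probe sets, which are not independent replicates, the log2 differences RA minus Control and Ro minus Control correlated at Pearson r = 0.744 and Spearman rho = 0.739, and 79.1% of probe sets had the same direction relative to the medians. Unchanged groups simulated with a common spread gave 0.499, 0.473 and 66.6%. An alternative added after seeing the data took a spread from the Control arrays and another, pooled, from the RA and Ro arrays. It gave 0.788, 0.681 and 75.0%. The observed covariance of 0.329 lay above the first simulated value, 0.160, and below the second, 0.413. Both simulations included the sharing of the Control arrays, and they do not settle whether the effects are related beyond it. The correlation was 0.582 without Control replicate 2, 0.912 without Control replicate 1 and 0.600 without RA replicate 2. Unchanged groups were not simulated with an array left out, so these values cannot be set against the simulated ones.

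Where Control lies between RA and Ro was read on the 1256 probe sets that met the centred 2-fold criterion, which were chosen without the Control arrays. For the 753 higher in RA, Control replicate 1 was nearer to RA for 68.4% and Control replicate 2 for 73.4%, and for the 503 lower in RA the figures were 54.3% and 44.5%. The share of the RA minus Ro difference that was RA minus Control replicate 1 was 0.88 for Cyp26b1 and 0.76 for Ccr9, whose Control signal was close to that in Ro. For P2rx7, Fam102b, Nt5e, Itga4 and Dhrs3 it was 0.04, -0.05, 0.09, 0.17 and 0.21, so that their signals on Control replicate 1 (759, 2784, 349, 1195 and 75.5) were close to those in RA. For Cma1, Nacc2 and Tph1 it was 0.23, 0.28 and 0.36. On Control replicate 2 the signals of P2rx7, Fam102b, Itga4 and Dhrs3 were 80.3, 75.0, 154 and 19.0, close to or below those in Ro, whereas that of Nt5e was 999, above both RA and Ro.

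**Figure D3:**
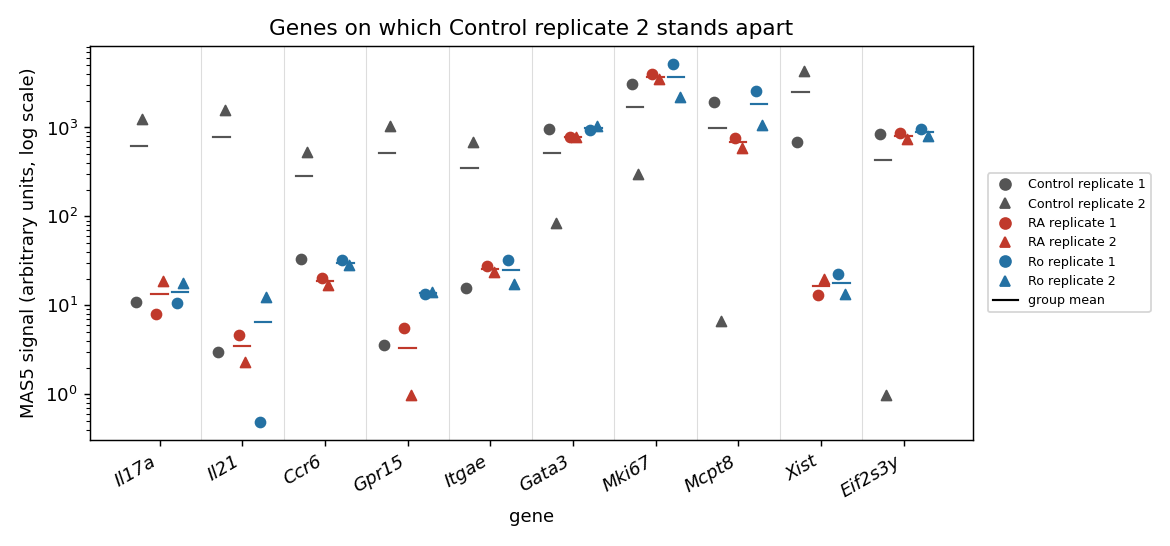
Signal of 10 genes on each array, on a log axis in arbitrary MAS5 units, with circles for replicate 1, triangles for replicate 2 and short lines for the mean of each group. Control replicate 2 alone is high for Il17a, Il21, Ccr6, Gpr15 and Itgae and low for Gata3, Mki67, Mcpt8 and Eif2s3y, and Xist is high on both Control arrays, at 680 and 4326.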

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

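The settings of the 4-array fit, its block included, camera on those 4 arrays, the simulation with a separate spread for the Control arrays and the directions of genes given as signals were chosen after the data were seen, and the other alternatives before. The count of 0 calls by limma on all 6 arrays (535, 1201 and 496 probe sets at an unadjusted p under 0.05) stayed at 0 in each comparison with either pseudocount, quantile normalization, no filter, the stricter filter, no intensity trend, gene means and the replicate block. Leaving out 1 of the 6 arrays gave 0 to 4372 calls for RA versus Control, 0 to 7211 for Ro versus Control, 0 to 12 for RA versus Ro and 0 to 4642 for the F-test. The highest counts against Control and in the F-test came without Control replicate 1, with the lone Control array assumed to vary like the other groups. RA versus Ro gave 12 without Control replicate 1 or Control replicate 2, and the F-test 7 without the latter. The 2-fold criterion without overlap gave 1852, 3013 and 1383 probe sets. The fit of only the RA and Ro arrays called 12, with quantile normalization 9, the stricter filter 4, a pseudocount of 1 11, a pseudocount at the median 12, and no intensity trend 0. All of these lay among the 12. Leaving out 1 array of that fit as well, with the lone array assumed to vary like the other group, gave 0 without RA replicate 1 or RA replicate 2, 551 without Ro replicate 1 and 425 without Ro replicate 2. The replicate block raised that count to 106, with the 12 among them. Deviations of arrays with the same number correlated at -0.01 for Control and RA, 0.01 for Control and Ro and 0.31 for RA and Ro. The numbers were not taken to pair the samples, since not every pair exceeded 0.1. That rule cannot decide for RA and Ro, because the pairs with Control contain Control replicate 2, which lay far from all other arrays. Whether the numbers pair the RA and Ro arrays stays open. Splitting the 4 arrays by replicate number called 4 probe sets against 12, but gave 2443 against 2030 at an unadjusted p under 0.05 and 1717 against 1256 by the centred 2-fold criterion. The remaining split gave 0, 289 and 711. In all but the calls, the split by replicate number thus separated the 4 arrays more widely than the labels did. A fit without a block leaves that difference in its spread, whatever the numbers mark. Gene lists called numbered 29, 28 with the replicate block, 25 to 43 without 1 array, and 0 with an estimated correlation or fry. The relation of the effects ran from 0.582 to 0.912 without 1 array, with 0.600 without RA replicate 2. List results that turned in the camera test had medians that ran, without 1 array, from -1.62 to 0.17 (Treg), -1.50 to 0.27 (glycolysis) and -1.68 to 0.0907 (unfolded protein response) for RA versus Control, from -1.21 to 0.25 (unfolded protein response) for Ro versus Control, and from -0.15 to 0.53 (Treg) and -0.37 to 1.40 (cell cycle) for RA versus Ro. The medians of 4 further lists crossed 0 without turning in that test, those of Th1 for RA versus Control (-1.50 to 0.01) and of T cell activation (-1.07 to 0.02), Treg (-1.81 to 0.00087) and naive and quiescence (-0.03 to 0.80) for Ro versus Control. Of 1030 values for the 51 gene results with a tested difference, 906 kept their side of the threshold, 124 gained a call and 0 turned direction. Most of the genes with a tested difference were named for a small p or a large difference on the same arrays, which by itself makes a turn unlikely. Of 181 further differences of named genes given as signals only, 67 turned when 1 array was left out, 51 of them without Control replicate 2. For RA versus Ro 12 of 51 turned, among them Tk1 (0.91, or -0.79 without Ro replicate 2). Of 348 values for 29 list results, 252 kept the call and 90 lost it. The cause was not tested. Median signals of 16.3 to 23.8 limit what dim genes can show.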

Other observations

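All tests of explanations in this part were chosen after the results were seen. Control replicate 2 carried a transcript profile that the other arrays lacked. Il17a, the signature cytokine of Th17 cells, had a signal of 1230 there and 8.01 to 18.9 elsewhere, Il21 had 1566, and the Th17 attractant Ccl20 had 771 against at most 2.55. The metallothioneins Mt1 and Mt2, zinc-binding stress proteins, stood at 6576 and 5869 and at no more than 109 and 53.1 on the other arrays. Timp1, a protease inhibitor, had 1909 against at most 15.8. Mki67, a proliferation marker, stood at only 299 against 2222 to 5196.

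Some transcripts of other blood cells differed between arrays of 1 group. Gzma, a granzyme of cytotoxic cells, had a signal of 1758 on Ro replicate 1 and 18.1 on Ro replicate 2. The platelet genes Pf4 and Ppbp had 459 and 501 on RA replicate 2 and 86.9 and 49.9 on RA replicate 1, and in Ro 1080 and 1065 on replicate 2 and 200 and 151 on replicate 1. Lyz2, a lysozyme of myeloid cells, stood at 1287 on Control replicate 1, 9.57 on Control replicate 2 and from 161 to 622 on the RA and Ro arrays. Prg2, an eosinophil granule gene, had 218 on Control replicate 1, 9.34 on Control replicate 2, 56.1 ± 8.33 (SD, n = 2) in RA and 24.4 ± 0.338 (SD, n = 2) in Ro.

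Control replicate 2 lay far from the other 5 arrays. A different scaling or signal distribution is argued against, because after quantile normalization 29.0% of probe sets still lay 2-fold or more from the mean of the other arrays, against at most 8.51% on any other array. A different amount or handling of the RNA stays open: the spike-in controls stood at 2.14 times the median of the other arrays there, against 0.826 to 1.14 elsewhere, and the ratio of 3' to 5' signal of Gapdh was 0.986, against 0.787 to 0.842. A culture in the cytokine mixture that only its label gives is a candidate explanation, though not one that Th17 genes single out. There 16 of 17 measured Th17 genes were above the mean of the other arrays, and their median deviation of 1.62 lay at percentile 100 of 10000 random lists matched on expression, but 11 of the 26 lists lay above percentile 95 and 5 of these had larger deviations (NK cell markers 2.98, CD8 T cell markers 2.49, Treg 2.02, glycolysis and hypoxia 1.92 and cytotoxic granule 1.80). Other activated or mixed cells stay open, as does whether the other arrays had the same culture and a difference in the sex of the donors.

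Xist was high on both Control arrays. Cells of female donors on Control replicate 2 may account for its share of this, since the median ratio of Y-linked probe sets there to the RA and Ro arrays was 0.0353, and Eif2s3y had 0.972 against 747 to 967. Control replicate 1 had both Xist at 680 and Eif2s3y at 855. A mixture of female and male cells there could be neither supported nor excluded, because Eif2s3y lay 1.52 SDs of the 4 RA and Ro arrays above the value predicted from Xist. Of the 6 Y-linked probe sets 5 lay within 2 SDs above that prediction, and a dim one of Kdm5d, at 35.9 against a mean of 24.1, lay 6.86 SDs above it. The prediction takes the Xist level of Control replicate 2 for that of female cells.

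Mast cell genes had lower values in RA than in Ro. A fall of mast cells and basophils alike and regulation of single genes cannot be told apart. The log2 difference of Cma1 and Tph1 lay at -2.57 (SE 0.57) relative to Mcpt8, Ms4a2 and Fcer1a, with a 95% half-width of 2.46, but these genes were selected because they passed the test, which by itself tends to make their difference look larger than that of other markers. For Cpa3 the value of -0.87 (SE 0.27) lay inside its half-width of 1.15. The limit was first set at 2 SE and was widened after the values were known, because 2 SE is too narrow for 2 arrays per group, and by that first limit both values would have lain outside. A loss of mast cells without basophils may also explain these genes, as Mcpt8 marks basophils, and regulation by retinoic acid was not tested separately.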
